A study of Homo sapiens with 39 samples.

How the data were processed

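RNA was measured by sequencing in 39 libraries of the JJN3 multiple myeloma line. Per the labels, cells grew in RPMI with 10% FCS, RNA was taken with Trizol, and libraries were made with the NEBNext Ultra RNA kit. The samples are labelled as T0 or as DMSO, GSK-J4 or ZnSO4 at 1, 3, 6 or 24 h; the protocol in the labels mentions 3, 6 and 24 h but not 1 h, and the sample labels were followed. Per the submitters' processing notes, the authors aligned reads with HISAT2 2.1.0 to hg19. The counting tool, its annotation and its strand setting, the read length and the doses are not given in the sources used here. The deposited table holds raw counts per gene, as whole numbers, per library, and the authors' counts were used as they stand.

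The table lists 57773 Ensembl identifiers. Of these, 51996 received a symbol from the name table, 342 from GENCODE 29 only, and 5435 have none. The reference annotation is of another genome build than the alignment, so it served for gene names, GC content and transcript length only, and no coordinates are given. Groups were the 13 combinations of treatment and time with 3 libraries each. Columns carry running sample numbers and a number after an S that does not follow their order and was not used. Replicates were numbered by their order within a group.

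Library totals ranged from 4347745 to 10695671 (median 6010529), with 21896 to 29200 genes holding a count. A floor of 3 counts equals 0.2805 to 0.69 CPM. For groups with 0 counts a fold is given as a lower bound from 3 counts over the group, for 1 to 3 counts as a ratio with an exact counting interval, and where neither group passes 3 counts none is given. Replicates were checked for duplicates by comparing counts gene by gene with counting noise, and none was found (chi-squared per gene 1.205 to 7.323 over the 39 pairs, highest between T0 libraries).

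Tests used R 4.3.3, edgeR 4.0.16 and limma 3.58.1. All 39 libraries were fitted together with edgeR's quasi-likelihood model (TMM factors, filterByExpr with a minimum count of 10, 1 coefficient per group), which kept 14460 genes with 26 residual degrees of freedom, 34.7 prior degrees of freedom, a common dispersion of 0.0023 and a biological coefficient of variation of 4.8%. F-tests were made for GSK-J4 against DMSO, ZnSO4 against DMSO and GSK-J4 against ZnSO4 at each time, DMSO against T0 at each time, and the difference between the 24 h and 6 h effects of each compound. Adjusted p-values are Benjamini-Hochberg values from edgeR within a comparison, and a gene counts as changed at adjusted p under 0.05. The standard error is the size of the log2FC over the square root of F. Levels are TMM-scaled CPM.

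Gene lists were written from general knowledge before the data were seen: metallothioneins, zinc exporters (SLC30), zinc importers (SLC39), cytosolic heat shock, ATF4 targets, cytosolic tRNA synthetases, ER chaperones and unfolded protein response, NRF2 targets, hypoxia response, cholesterol synthesis, immediate early genes, NF-kB targets, interferon-stimulated genes, p53 targets, BCL2 family, plasma cell identity, MYC and ribosome biogenesis, S phase and G1/S, G2/M, H3K27 methylation enzymes and KDM5, mitochondrially encoded mRNAs, and markers of other cell types. List names are short labels: the cytosolic heat shock list also holds SERPINH1, HSPD1 and HSPE1, whose products lie outside the cytosol. Of 423 entries 418 matched an identifier (CCL3, CCL4, BOP1, UHRF1 and PECAM1 did not). The 22 lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated per list. Members were also adjusted over the list alone.

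Named genes follow a rule fixed beforehand: the 6 largest rises and 6 largest falls per comparison (4 and 4 against T0 and between times) among genes with adjusted p under 0.05, average log2 CPM of at least 1, a symbol and no overlap between the groups' libraries, immunoglobulin genes left out; the metallothioneins, SLC30A1, HMOX1, ATF4, ATF3, DDIT3, CHAC1, TRIB3, ASNS, MYC, IRF4, KDM6A, KDM6B, HSPA1A and HSPA1B where detected; and up to 4 members per list with the smallest p.

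The pipeline was tested on simulated data with the depth of GSK-J4 and DMSO at 6 h, 13699 genes and 200 changed. The changed genes were drawn from those with a DMSO mean over 2 CPM, and counts followed the dispersions fitted to the real libraries. It called 62.5% of 72 genes changed 1.5-fold, 88.3% of 60 changed 2-fold and 100% of 68 changed 4-fold (DESeq2: 59.7%, 83.3% and 100%); 8 of its 174 calls (4.6%) fell on unchanged genes, and 0 genes were called between simulated groups without a change.

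Alternatives set beforehand were RLE size factors, library totals, no filter, DESeq2 1.42.0, fitting only the groups compared, leaving out each library, an estimated correlation for the lists, and a 2-fold limit for the shared response. Fits without the 24 h libraries, with only these, or with a replicate block by order within the group were added after seeing the data. Every comparison was also repeated over the other splits of its libraries, 10 per pair of groups and 100 for the difference between times. The shared response to the compounds was set beside 20 simulations per time of unchanged groups. In these, treated and DMSO libraries were all drawn from the DMSO means, and both treated groups were compared with the same simulated DMSO libraries. Figures were drawn with matplotlib.

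Reads shared between similar genes (metallothionein copies, FTH1 and HSPA8 and their pseudogenes, mitochondrial genes and their nuclear copies) cannot be divided from a count table. Protein, histone marks and metal content are not analysed here.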

Results

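The count table covers 39 libraries of the multiple myeloma line JJN3, 3 in each of 13 groups. The groups are cells at the start (T0), and cells kept in DMSO, GSK-J4 or ZnSO4 for 1, 3, 6 or 24 h. GSK-J4 inhibits the KDM6 family of histone H3K27 demethylases, and ZnSO4 supplies zinc. Doses are not given in the sources used here. The comparisons ask what each compound changes against its vehicle at the same time, how the compounds differ, how DMSO groups differ from T0, and whether an effect differs between 6 and 24 h. Libraries held 4347745 to 10695671 counts (median 6010529), and 14460 genes passed the filter on low counts. Levels are in CPM (counts scaled to library size) as mean ± SD, and log2 fold changes (log2FC) carry their standard error, n = 3 libraries per group throughout. The p-values measure only the spread between these libraries, which may be technical, since the labels do not say that replicates were separate cultures. The library strand is not marked, so reads from an overlapping antisense gene cannot be told from the named gene's own.

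The largest division among the libraries is time. The first principal component holds 54.44% of the variance and parts the 9 libraries of 24 h from the other 30, while on the second (7.75%) the treated libraries of 3, 6 and 24 h lie apart from those of T0 and DMSO. Mitochondrially encoded genes made up 4.376 to 5.542% of counts in the 24 h libraries and 2.921 to 3.902% in all earlier ones.

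**Figure D1:**
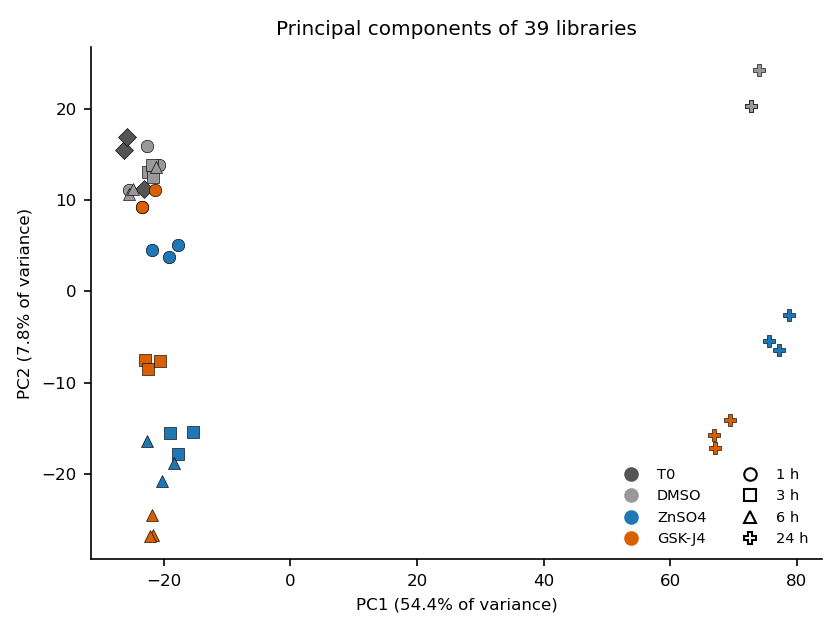
Each point is 1 of 39 libraries on the first and second principal components (axes in component units, with the percentage of variance), coloured by treatment and shaped by time. All 9 libraries of 24 h lie to the right on the component with 54.44% of the variance.

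At 1 h, GSK-J4 raised genes of zinc handling before almost anything else. MT1X (ENSG00000187193) encodes a metallothionein, a small cysteine-rich protein that binds zinc and copper, and rose from 10.3 ± 4.30 CPM in DMSO to 53.2 ± 3.89 CPM (log2FC 2.34 ± 0.15, adjusted p = 5.8e-19). MT2A (ENSG00000125148), another metallothionein, rose as well (log2FC 2.06 ± 0.28, adjusted p = 1.6e-06; 3.07 without replicate 1 of DMSO at 1 h). SLC30A1 (ENSG00000170385), whose product exports zinc from the cytosol, rose from 66.6 ± 6.88 to 172 ± 12.8 CPM (log2FC 1.38 ± 0.08, adjusted p = 7.3e-22). TIPARP (ENSG00000163659), an ADP-ribosyltransferase gene induced by the aryl hydrocarbon receptor, fell from 135 ± 3.10 to 77.1 ± 8.07 CPM (log2FC −0.80 ± 0.06, adjusted p = 1.1e-14). DUSP6, which encodes a phosphatase of ERK, fell with log2FC −0.62 ± 0.09 (adjusted p = 2.8e-06). MT-CO3 (ENSG00000198938), a mitochondrially encoded subunit of cytochrome c oxidase, fell slightly (log2FC −0.34 ± 0.05, adjusted p = 5.9e-05).

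Only 15 genes changed at 1 h of GSK-J4 (5 higher, 10 lower; 575 at unadjusted p under 0.05), and 10 without replicate 3 of DMSO. Of 8 measured metallothioneins 3 rose and 5 did not pass (list test adjusted p = 1.3e-51), and 5 rose when adjusted over the list alone. MT1G was among the 3 (log2FC 1.70 ± 0.31, adjusted p = 0.0012), but its call ended with DESeq2 and its log2FC was 4.76 without replicate 1 of DMSO. Mitochondrially encoded mRNAs fell in 4 of 13 (9 did not pass; list adjusted p = 1.75e-19), and in 9 when adjusted over the list alone. Reads of all mitochondrially encoded genes, those of rRNA and tRNA included, made up 3.297 ± 0.101% of counts against 3.63 ± 0.059% in DMSO. The zinc exporters of the SLC30 family were called as a list (adjusted p = 1.25e-10) through SLC30A1 alone, with a median log2FC of 0.04 over 7 genes and a mean of −0.013.

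By 3 h the metallothioneins dominated the response to GSK-J4. MT1X reached 577 ± 22.8 CPM against 7.25 ± 1.15 CPM in DMSO (log2FC 6.34 ± 0.13, adjusted p = 9.4e-46). MT2A reached 281 ± 15.8 against 2.27 ± 0.229 CPM (log2FC 6.93 ± 0.18, adjusted p = 8.2e-40). MT1H had 4915 counts over the GSK-J4 libraries and 2 over DMSO, a ratio of 1490 after scaling (95% counting interval 411 to 12300). MT1E, with 0 counts in DMSO, was at least 105-fold higher. Metallothionein copies resemble each other, so the share of reads between them is uncertain. SLC30A1 is a different kind of gene and rose to 354 ± 13.9 CPM (log2FC 2.33 ± 0.07, adjusted p = 9.3e-36). CHAC1 (ENSG00000128965), which degrades glutathione and is a target of the amino acid stress factor ATF4, rose from 49.3 ± 6.99 to 246 ± 7.48 CPM (log2FC 2.30 ± 0.14, adjusted p = 6.7e-21). DDIT3 (ENSG00000175197), encoding the stress factor CHOP, rose from 5.53 ± 0.753 to 23.1 ± 0.173 CPM (log2FC 2.08 ± 0.15, adjusted p = 7.8e-18). SLC39A10 (ENSG00000196950), a zinc importer gene, fell from 24.1 ± 2.73 to 13.4 ± 0.532 CPM (log2FC −0.83 ± 0.11, adjusted p = 1.5e-07). GPR15, a receptor gene, fell with log2FC −1.09 ± 0.13 (adjusted p = 2.1e-09).

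In all, 344 genes changed at 3 h of GSK-J4 (210 higher, 134 lower; 37 and 11 at least 2-fold), and 1072 when only the GSK-J4 and DMSO libraries of 3 h were fitted (495 higher, 577 lower). ATF4 targets rose in 27 of 33 with 6 not passing (list adjusted p = 2.38e-125; 30 when adjusted over the list alone), among them SESN2 (log2FC 1.71 ± 0.09) and STC2 (1.53 ± 0.07). Hypoxia response genes rose in 6 of 19 with 13 not passing (list adjusted p = 1.21e-15; 11 when adjusted over the list alone), with VEGFA, a vascular growth factor, at 1.17 ± 0.06. Cytosolic tRNA synthetases rose in 8 of 20 with 12 not passing (list adjusted p = 6.04e-07; 10 rose and 1 fell when adjusted over the list alone). Of the mitochondrially encoded mRNAs 2 rose, 7 fell and 4 did not pass (list adjusted p = 2.1e-16), MT-CO3 with log2FC −0.68 ± 0.05. Genes of ER chaperones and the unfolded protein response rose in 5 of 26 (list adjusted p = 0.00499; adjusted p = 0.214 with an estimated correlation), including ERN1, the sensor kinase IRE1 (0.95 ± 0.08), and HERPUD1 (0.91 ± 0.05). The median of the list was −0.02 and its mean 0.08.

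At 6 h of GSK-J4, most targets of the amino acid stress factor ATF4 rose. CHAC1 reached 370 ± 21.6 CPM against 40.4 ± 18.8 CPM in DMSO (log2FC 3.19 ± 0.14, adjusted p = 4.6e-28). SESN2 (ENSG00000130766), which restrains mTORC1 when leucine is short, rose from 44.1 ± 9.90 to 285 ± 15.7 CPM (log2FC 2.69 ± 0.09, adjusted p = 3.1e-35). PSAT1 (ENSG00000135069) of serine synthesis rose from 214 ± 11.9 to 810 ± 41.2 CPM (log2FC 1.92 ± 0.05, adjusted p = 1.3e-38). The glycine transporter gene SLC6A9 and the asparagine synthetase gene ASNS rose with log2FC 2.15 ± 0.07 and 1.45 ± 0.07 (adjusted p = 3.1e-34 and 3.5e-26). Of the BCL2 family, HRK rose with log2FC 1.91 ± 0.29, BBC3 with 1.33 ± 0.15 and PMAIP1 with 1.08 ± 0.07 (adjusted p = 4.9e-07, 6.5e-11 and 2.6e-19). MT2A stood at 499 ± 15.8 against 1.55 ± 0.514 CPM (log2FC 8.33 ± 0.18, adjusted p = 7.1e-45). SLC30A1 was at 233 ± 6.01 against 61.7 ± 10.2 CPM (log2FC 1.91 ± 0.08, adjusted p = 2.1e-30). The oncogene MYC (ENSG00000136997) fell from 947 ± 183 to 544 ± 17.5 CPM (log2FC −0.80 ± 0.09, adjusted p = 1.3e-10). Nucleolin, NCL (ENSG00000115053), fell from 2155 ± 49.3 to 1569 ± 18.7 CPM (log2FC −0.46 ± 0.05, adjusted p = 1.4e-11). ID3, an inhibitor of helix-loop-helix factors, and LRFN1 fell with log2FC −1.56 ± 0.32 and −1.53 ± 0.16 (adjusted p = 0.00015 and 1.1e-11).

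GSK-J4 changed 2947 genes at 6 h (1422 higher, 1525 lower; 240 and 43 at least 2-fold), and scaling by library totals alone turned this into 1791 higher and 1117 lower. All 33 ATF4 targets passed, 31 rising and 2 falling (list adjusted p = 3.1e-15 with an estimated correlation). Genes of MYC and ribosome biogenesis fell in 20 of 21 with 1 not passing (list adjusted p = 3.31e-19), and all 21 fell when adjusted over the list alone. Heat shock genes fell in 13 of 18, with 1 rising and 4 not passing (list adjusted p = 7.19e-11). HSPA8, a constitutive chaperone gene with pseudogenes that may share its reads, fell with log2FC −1.10 ± 0.09. Of the 20 tRNA synthetases 12 rose, 4 fell and 4 did not pass (list adjusted p = 6.32e-20). Of the 14 genes of the BCL2 family 5 rose, 1 fell and 8 did not pass (list adjusted p = 0.00477). Cholesterol synthesis genes fell in 10 of 21, with 1 rising and 10 not passing (list adjusted p = 0.000117; 12 fell when adjusted over the list alone), SQLE with log2FC −0.44 ± 0.06. Mitochondrially encoded mRNAs fell in 10 of 13 with 2 rising and 1 not passing (list adjusted p = 3.13e-13), MT-CO3 with log2FC −0.95 ± 0.06.

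After 24 h of GSK-J4 metallothioneins and SLC30A1 were still higher than in DMSO, and CCNB1, MYC and NCL were lower. MT2A stood at 548 ± 25.9 against 4.52 ± 2.25 CPM (log2FC 6.96 ± 0.15, adjusted p = 5.1e-45), MT1X at 511 ± 40.2 against 18.3 ± 1.59 CPM (log2FC 4.81 ± 0.11, adjusted p = 7.7e-44). SLC30A1 was at 199 ± 4.47 against 114 ± 3.50 CPM (log2FC 0.81 ± 0.07, adjusted p = 2.3e-14). CHAC1 had dropped to 1.81 ± 0.0899 CPM in DMSO and was 10.7 ± 1.92 CPM with GSK-J4 (log2FC 2.55 ± 0.43, adjusted p = 2.8e-06). DDIT3 rose from 33.4 ± 2.55 to 94.1 ± 4.61 CPM (log2FC 1.5 ± 0.09, adjusted p = 1.6e-21). CDKN1A (ENSG00000124762), the cyclin-dependent kinase inhibitor p21, rose from 8.76 ± 0.564 to 21.9 ± 4.36 CPM (log2FC 1.32 ± 0.17, adjusted p = 3.3e-09). Cyclin B1, CCNB1 (ENSG00000134057), fell from 35.5 ± 1.76 to 14.5 ± 0.829 CPM (log2FC −1.29 ± 0.14, adjusted p = 4.6e-11). NCL fell from 3194 ± 29.4 to 1937 ± 46.1 CPM (log2FC −0.72 ± 0.05, adjusted p = 2.5e-19) and MYC with log2FC −0.67 ± 0.09 (adjusted p = 9.1e-09). GPR37, a receptor gene, fell with log2FC −1.74 ± 0.35 (adjusted p = 5.5e-05).

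The 24 h comparison of GSK-J4 with DMSO called 4629 genes (2205 higher, 2424 lower; 282 and 64 at least 2-fold), or 3256 higher and 1526 lower with library totals alone as the scale. ATF4 targets rose in 29 of 33, with 2 falling and 2 not passing (list adjusted p = 5.51e-56), PCK2 of mitochondrial gluconeogenesis with log2FC 1.57 ± 0.09. Genes of MYC and ribosome biogenesis fell in 19 of 21 with 2 not passing (list adjusted p = 5.2e-25), NPM1 with −0.61 ± 0.05 and NOP56 with −0.60 ± 0.05. G2/M genes fell in 13 of 22 with 9 not passing (list adjusted p = 1.84e-06; adjusted p = 0.232 with an estimated correlation), and 15 fell when adjusted over the list alone. Genes of S phase and G1/S fell in 14 of 21, with 2 rising and 5 not passing (list adjusted p = 0.00593; adjusted p = 0.145 with an estimated correlation). Heat shock genes fell in 12 of 18 and 3 rose (list adjusted p = 3.53e-07, or 0.145 with an estimated correlation). Hypoxia response genes fell in 9 of 19 and 1 rose (list adjusted p = 0.00968; adjusted p = 0.131 with an estimated correlation). ER chaperone and unfolded protein response genes rose in 11 of 26, with 3 falling (list adjusted p = 7.66e-05; adjusted p = 0.111 with an estimated correlation), DNAJB9 with 1.02 ± 0.07.

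**Figure D2:**
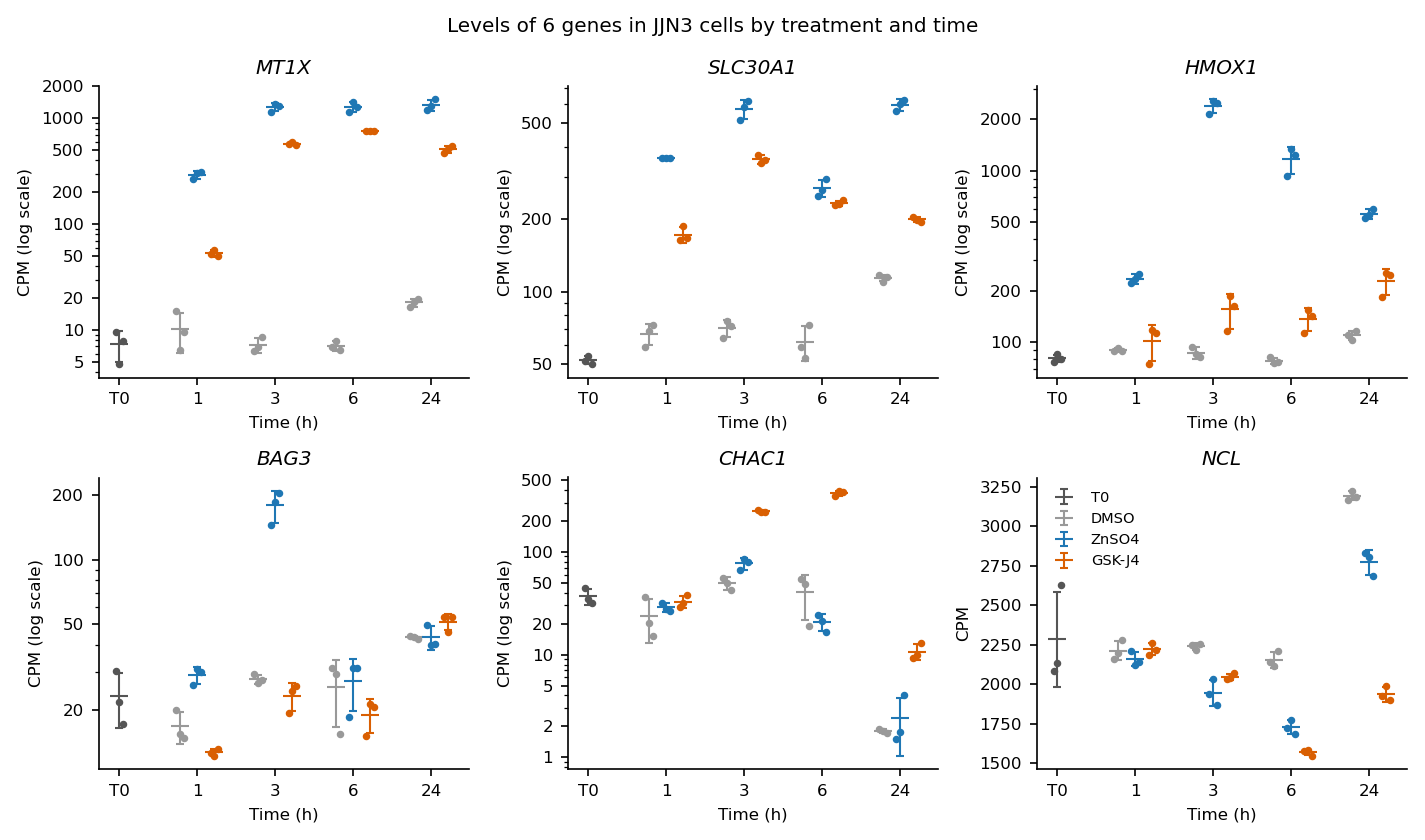
Levels in CPM (vertical axes, logarithmic except NCL) of 6 genes against time in hours, with each library as a point and bars for mean and SD of 3 libraries in T0, DMSO, ZnSO4 and GSK-J4. MT1X and SLC30A1 are higher with either treatment from 1 h on, and HMOX1 and BAG3 have their highest mean with ZnSO4 at 3 h. CHAC1 has its highest with GSK-J4 at 6 h (370 CPM), and NCL its lowest there (1569 CPM).

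Of the genes of the enzymes that GSK-J4 inhibits, KDM6B rose moderately at 24 h and KDM6A had no call. KDM6A (ENSG00000147050) was not called with GSK-J4 at any time (log2FC 0.14 ± 0.10, 0.31 ± 0.10, 0.24 ± 0.10 and 0.15 ± 0.10 at 1, 3, 6 and 24 h; adjusted p = 1, 0.1, 0.092 and 0.3). KDM6B (ENSG00000132510) rose at 24 h from 9.38 ± 1.09 to 13.9 ± 1.12 CPM (log2FC 0.56 ± 0.16, adjusted p = 0.0047), and its call at 3 h (0.51 ± 0.13, adjusted p = 0.012) was lost without replicate 3 of GSK-J4 (0.42). With ZnSO4 at 3 h both genes rose, KDM6A with log2FC 0.58 ± 0.10 and KDM6B with 0.71 ± 0.13 (adjusted p = 1.6e-05 and 3.9e-05). Over the 10 genes of H3K27 methylation enzymes and KDM5, 0, 1, 2 and 1 rose and 0, 0, 0 and 1 fell with GSK-J4 at 1, 3, 6 and 24 h, and 0, 3, 1 and 1 rose with ZnSO4. The list was not called at any time (lowest adjusted p = 0.0652, ZnSO4 at 3 h). The gene that fell was EED (log2FC −0.71 ± 0.08, adjusted p = 7.6e-11), a core subunit of the H3K27 methyltransferase PRC2.

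ZnSO4 raised the same zinc genes. At 1 h MT1X reached 293 ± 24.5 CPM (log2FC 4.8 ± 0.12, adjusted p = 1.7e-40), MT2A 83.4 ± 11.5 CPM (log2FC 4.69 ± 0.19, adjusted p = 2.4e-29; 5.70 without replicate 1 of DMSO) and SLC30A1 359 ± 1.23 CPM (log2FC 2.44 ± 0.07, adjusted p = 9.9e-37). DNAJB1 (ENSG00000132002), a co-chaperone of HSP70, rose from 136 ± 39 to 572 ± 86.8 CPM (log2FC 2.06 ± 0.16, adjusted p = 1.7e-15). HMOX1 (ENSG00000100292), the haem oxygenase, rose from 89.8 ± 2.29 to 234 ± 15.1 CPM (log2FC 1.39 ± 0.12, adjusted p = 4.8e-14). The plasma cell factor IRF4 (ENSG00000137265) fell from 868 ± 56.5 to 575 ± 38.1 CPM (log2FC −0.60 ± 0.06, adjusted p = 3.5e-11) and PRDM1, the factor BLIMP1, with log2FC −0.46 ± 0.07 (adjusted p = 1.3e-06).

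Within 1 h of ZnSO4, 98 genes changed (72 higher, 26 lower; 22 and 2 at least 2-fold). Immediate early genes rose in 10 of 19 with 9 not passing (list adjusted p = 9.83e-24), EGR1 with log2FC 1.96 ± 0.33 and JUN with 0.88 ± 0.09. Heat shock genes rose in 8 of 18 with 10 not passing (list adjusted p = 1.96e-25), and metallothioneins in 7 of 8. In the plasma cell identity list 2 of 16 fell (list adjusted p = 1.88e-06; adjusted p = 0.0602 with an estimated correlation).

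At 3 h of ZnSO4, HMOX1 and heat shock genes were strongly raised. HMOX1 rose to 2393 ± 217 CPM against 86.8 ± 6.56 CPM in DMSO (log2FC 4.78 ± 0.12, adjusted p = 2.2e-41). HSPA6 (ENSG00000173110), a strictly inducible HSP70 gene, rose from 2.66 ± 0.801 to 116 ± 20.8 CPM (log2FC 5.39 ± 0.25, adjusted p = 8.9e-27). BAG3 (ENSG00000151929), a co-chaperone of protein clearance, rose from 27.7 ± 1.34 to 179 ± 30.7 CPM (log2FC 2.69 ± 0.13, adjusted p = 1.9e-25). MT1X stood at 1272 ± 112 CPM (log2FC 7.48 ± 0.13, adjusted p = 1.3e-50) and SLC30A1 at 573 ± 52.1 CPM (log2FC 3.03 ± 0.07, adjusted p = 2.7e-42). MT1E, with 0 counts in DMSO, was at least 586-fold higher. MT1H had 8231 counts against 2, a ratio of 3010 (95% counting interval 833 to 24900). SLC7A11, the cystine transporter gene, rose with log2FC 1.95 ± 0.11 (adjusted p = 5.7e-22). The chemokine receptor gene CCR2 fell with log2FC −2.27 ± 0.44 and the matrix protein gene TGFBI with −1.95 ± 0.45 (adjusted p = 0.00011 and 0.0011), the latter −2.69 without replicate 1 of ZnSO4. SLC39A10 fell from 24.1 ± 2.73 to 10.8 ± 0.745 CPM (log2FC −1.14 ± 0.12, adjusted p = 2.8e-11) and IRF4 with log2FC −0.69 ± 0.06 (adjusted p = 2.2e-14).

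For 3 h of ZnSO4, 1555 genes changed (953 higher, 602 lower; 137 and 25 at least 2-fold). With library totals alone as the scale the balance turned to 758 higher and 947 lower. All 18 genes of the heat shock list rose (list adjusted p = 1.47e-07 with an estimated correlation). NRF2 targets rose in 12 of 18 with 6 not passing (list adjusted p = 8.75e-06 with an estimated correlation), GCLM of glutathione synthesis with log2FC 1.06 ± 0.06. Hypoxia response genes rose in 13 of 19 with 6 not passing (list adjusted p = 7.19e-08 with an estimated correlation). ATF4 targets rose in 24 of 33 with 9 not passing (list adjusted p = 1.38e-45), immediate early genes in 13 of 19 with 1 falling (list adjusted p = 2.43e-17). The BCL2 family rose in 6 of 14 with 8 not passing (list adjusted p = 1.63e-09), BBC3 with 1.43 ± 0.15 and BMF with 1.11 ± 0.07. Genes of MYC and ribosome biogenesis fell in 13 of 21 with 8 not passing (list adjusted p = 1.63e-10; 16 fell when adjusted over the list alone). NF-kB targets rose in 4 of 13 (list adjusted p = 0.0153), the ubiquitin-editing enzyme gene TNFAIP3 with 0.40 ± 0.07.

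At 6 and 24 h of ZnSO4, HMOX1, NQO1 and SLC30A1 were still higher than in DMSO. HMOX1 was at 1168 ± 213 CPM at 6 h (log2FC 3.90 ± 0.12, adjusted p = 9.6e-37) and 562 ± 36.7 CPM at 24 h (log2FC 2.36 ± 0.11, adjusted p = 6.3e-26). NQO1, an NRF2-driven quinone reductase gene, rose with log2FC 0.91 ± 0.07 and 0.98 ± 0.07 (adjusted p = 8.4e-16 and 7.1e-18). The small heat shock protein gene HSPB1 (ENSG00000106211) rose from 11.6 ± 0.914 to 52.0 ± 6.87 CPM at 6 h and from 13.1 ± 0.736 to 37.9 ± 6.01 CPM at 24 h (log2FC 2.16 ± 0.12 and 1.53 ± 0.13, adjusted p = 1.7e-22 and 4.3e-15). FTH1, the ferritin heavy chain, rose with log2FC 1.73 ± 0.07 and 1.54 ± 0.07 (adjusted p = 7.3e-29 and 1.2e-26), though its reads may be shared with pseudogenes. SLC30A1 was at 269 ± 22.2 CPM at 6 h and 596 ± 33.6 CPM at 24 h (log2FC 2.13 ± 0.08 and 2.39 ± 0.07, adjusted p = 7.5e-33 and 3.5e-38). MT1M, with 0 counts in DMSO, was at least 139-fold and at least 177-fold higher. SLC39A10 fell at 6 h from 27.5 ± 4.03 to 11.3 ± 0.525 CPM and at 24 h from 9.72 ± 0.437 to 4.72 ± 0.262 CPM (log2FC −1.28 ± 0.12 and −1.04 ± 0.19, adjusted p = 3.5e-12 and 6.1e-05). At 6 h GPRC5D (ENSG00000111291), a surface antigen of myeloma cells, fell from 10.0 ± 2.12 to 4.43 ± 1.22 CPM (log2FC −1.16 ± 0.22, adjusted p = 0.00017). CHAC1 fell from 40.4 ± 18.8 to 20.8 ± 3.83 CPM (log2FC −0.97 ± 0.20, adjusted p = 0.0005), although replicate 3 of DMSO, at 19 CPM, lay among the ZnSO4 libraries (16.7 to 24.3 CPM).

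ZnSO4 changed 1348 genes at 6 h (696 higher, 652 lower; 110 and 5 at least 2-fold) and 1382 at 24 h (575 higher, 807 lower; 82 and 15 at least 2-fold). Leaving out libraries, 876 were called at 6 h without replicate 3 of ZnSO4, and 809 at 24 h without replicate 2. NRF2 targets rose in 10 and 12 of 18 with none falling (list adjusted p = 7.25e-06 and 4.19e-05 with an estimated correlation). Cytosolic tRNA synthetases fell in 8 and 10 of 20 (list adjusted p = 0.000281 and 2.34e-06), and genes of MYC and ribosome biogenesis in 14 and 13 of 21 (list adjusted p = 1.82e-13 and 2.96e-11). The plasma cell identity list fell in 8 of 16 at each time (list adjusted p = 1.96e-07 and 0.0001; the 24 h call was lost, adjusted p = 0.117 with an estimated correlation), with TNFRSF17, the antigen BCMA, at log2FC −0.46 ± 0.08 and POU2AF1 at −0.58 ± 0.08 at 6 h. ER chaperone and unfolded protein response genes fell in 10 of 26 at each time (list adjusted p = 0.00021 and 0.00012; adjusted p = 0.0812 and 0.0866 with an estimated correlation). Zinc importers of the SLC39 family fell in 4 of 11 at 6 h (list adjusted p = 0.00432) and in 3 at 24 h (list adjusted p = 0.0486; adjusted p = 0.0866 with an estimated correlation). Of the heat shock list 8 rose and 2 fell at 6 h (list adjusted p = 2.53e-08; adjusted p = 0.0812 with an estimated correlation), and 4 rose and 3 fell at 24 h without a call (list adjusted p = 0.227). ATF4 targets had no list call at either time, with 7 rising and 4 falling at 6 h and 5 of each at 24 h (list adjusted p = 0.738 and 0.489).

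**Figure D3:**
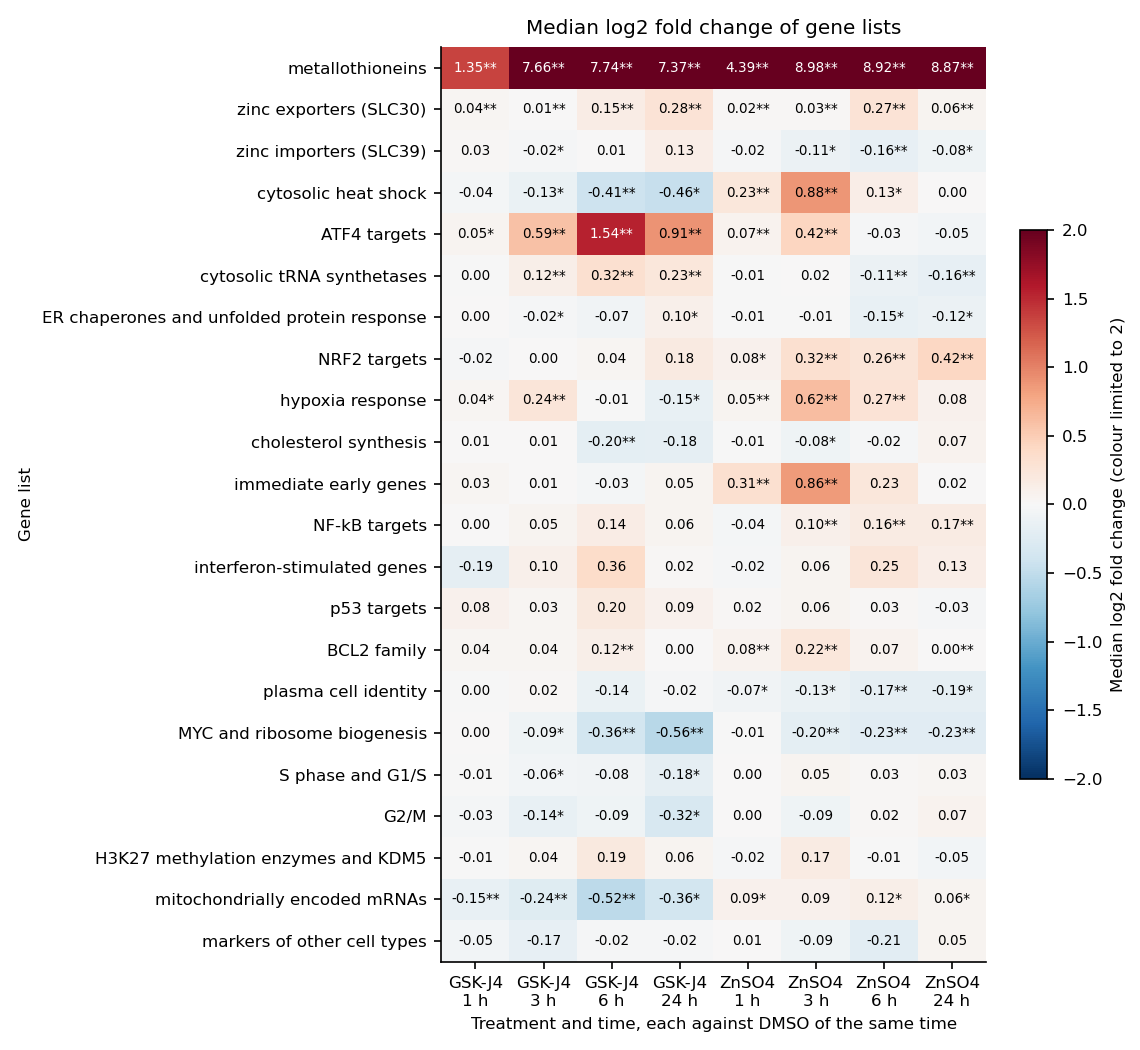
Median log2 fold change (colour and numbers) of the 22 gene lists (vertical axis) for GSK-J4 and ZnSO4 against DMSO of the same time (horizontal axis); 1 star marks a called list and 2 stars a call that holds with an estimated correlation. Metallothioneins are high in every column after 1 h, ATF4 targets with GSK-J4 at 6 h (median 1.54) and heat shock genes with ZnSO4 at 3 h (median 0.88).

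Interferon-stimulated genes had no call with either compound at any time: with GSK-J4 0, 0, 2 and 1 of 13 rose and 1 fell at 24 h. With ZnSO4 0, 1, 2 and 1 rose and 1 fell at 24 h. The p53 targets also had none, with 6 of 17 rising and 3 falling at 6 h of GSK-J4 (list adjusted p = 0.109). Markers of other cell types, 8 of them measured, had no call with GSK-J4, while 2 fell at 3 h of ZnSO4. These were COL1A1 and COL1A2 (log2FC −1.23 ± 0.38 and −1.46 ± 0.43), and both calls were lost without replicate 3 of DMSO (−0.58 and −0.79). With GSK-J4 at 3 h both moved the same way without a call (−0.97 ± 0.35 and −1.16 ± 0.39). NF-kB targets were not called with GSK-J4 (4 rising and 2 falling of 13 at 6 h, list adjusted p = 0.109) but were at 6 and 24 h of ZnSO4, with 3 rising each time (list adjusted p = 0.00493 and 0.00332). Immediate early genes were not called with GSK-J4, although 5 rose and 5 fell of 19 at 6 h, where the median was −0.03, the mean 0.16 and the test pointed down (list adjusted p = 0.867). NRF2 targets were not called with GSK-J4 either, with 4 rising and 3 falling of 18 at 6 h and 8 and 6 at 24 h (list adjusted p = 0.685 and 0.129). HMOX1 itself rose at 3 h with log2FC 0.84 ± 0.12 (adjusted p = 7.8e-07) and at 24 h with 1.06 ± 0.12 (adjusted p = 4.7e-11). At 6 h its GSK-J4 libraries (113.5 to 154.1 CPM) lay above those of DMSO (75.75 to 81.59 CPM).

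Zinc importers showed 2 rising and 3 falling of 11 at 6 h of GSK-J4 without a call (list adjusted p = 0.749). Zinc exporters rose in 2 of 7 at 3 and at 6 h and in 4 at 24 h of GSK-J4 with 1 falling (list adjusted p = 1.82e-11, 0.000114 and 0.00823), the Golgi transporter gene SLC30A7 with log2FC 0.54 ± 0.08 at 24 h. Mitochondrially encoded mRNAs, lower with GSK-J4, were not lower with ZnSO4: 3 of 13 rose and none fell at 6 h (list adjusted p = 0.0285; adjusted p = 0.487 with an estimated correlation).

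Compared directly, GSK-J4 and ZnSO4 parted on heat shock, NRF2 and ATF4 genes. At 3 h HSPA6 was lower with GSK-J4 by log2FC −5.06 ± 0.22, HMOX1 by −3.94 ± 0.11 and BAG3 by −2.95 ± 0.13 (adjusted p = 2e-28, 5.1e-38 and 2.1e-28), while CHAC1 was higher (log2FC 1.67 ± 0.13, adjusted p = 7.7e-17). At 6 h CHAC1 was higher with log2FC 4.16 ± 0.16 and INHBE (ENSG00000139269), an activin subunit induced by ATF4, stood at 66.9 ± 2.66 against 4.35 ± 0.822 CPM (log2FC 3.93 ± 0.17; adjusted p = 5.7e-31 and 2.6e-28). BAMBI, a decoy receptor of TGF-beta signalling, was higher with log2FC 3.01 ± 0.11 and FUT1 with 3.31 ± 0.18 (adjusted p = 4e-33 and 2.3e-23). MT1X was lower with GSK-J4 at 1, 3, 6 and 24 h (log2FC −2.46 ± 0.10, −1.14 ± 0.08, −0.76 ± 0.08 and −1.39 ± 0.08; adjusted p = 8.4e-30, 2e-19, 2e-12 and 9.6e-23). SLC30A1 was lower at 1, 3 and 24 h (−1.06 ± 0.07, −0.70 ± 0.06 and −1.58 ± 0.07; adjusted p = 1.3e-19, 3.5e-14 and 1.2e-28). At 6 h SLC30A1 was lower by −0.21 ± 0.07 (adjusted p = 0.018), a call that was lost without the filter, without replicate 3 of ZnSO4, and without replicate 1 or 2 of GSK-J4. At 24 h the drug efflux pump gene ABCB1 and the extracellular chaperone gene CLU were lower with GSK-J4 (log2FC −1.96 ± 0.32 and −1.79 ± 0.17, adjusted p = 2.4e-06 and 2.1e-13).

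Between the treated groups 96, 1462, 2661 and 3546 genes differed at 1, 3, 6 and 24 h (20, 577, 1233 and 1734 higher with GSK-J4; 76, 885, 1428 and 1812 lower). Scaling by library totals alone gave 1270 higher and 638 lower at 3 h, 1528 and 1181 at 6 h, and 2447 and 1229 at 24 h. Metallothioneins were lower with GSK-J4 in 6, 8, 8 and 8 of 8. Heat shock genes were lower in 9, 18, 15 and 10 of 18, with 1 higher at 24 h (list adjusted p = 0.000573, 5.42e-09, 0.000842 and 0.0293 with an estimated correlation). ATF4 targets were higher in 12 of 33 and lower in 4 at 3 h (list adjusted p = 0.000527; adjusted p = 0.0693 with an estimated correlation), in 30 against 1 at 6 h and in 27 against 1 at 24 h (list adjusted p = 4.73e-15 and 1.12e-09 with an estimated correlation). NRF2 targets were lower in 14, 14 and 10 of 18 at 3, 6 and 24 h with none higher, GCLM at 3 h with log2FC −1.01 ± 0.06.

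Many genes moved in the same direction with both compounds. At 1, 3, 6 and 24 h, 7, 189, 559 and 774 genes were called in the same direction and 0, 12, 86 and 110 in opposite ones. MT1X, MT2A and SLC30A1 were among those higher at every time. From the sizes of the lists alone, 13.8 shared rises and 5.58 shared falls would arise at 3 h (observed 137 and 52), 68.4 and 68.8 at 6 h (218 and 341), and 87.7 and 135 at 24 h (250 and 524). The log2FC of all 14460 genes correlated with r = 0.410, 0.692, 0.572 and 0.510 at the successive times. Because the same DMSO libraries serve both comparisons, unchanged groups were simulated and measured against shared DMSO libraries that were simulated too. They gave r = 0.485, 0.576, 0.475 and 0.429, and at most 1 shared call in 20 simulations. Groups without a change give few calls of any kind, so that count does not measure what shared controls add among changed genes. Departures of single actual DMSO libraries are not part of these simulations. Those r values come from the 12654 to 13676 genes that passed the filter in each simulation, not from the 14460, so they are only a rough guide. The covariance was 0.0161, 0.0234, 0.0163 and 0.0152 in the simulations against 0.0308, 0.107, 0.114 and 0.105 observed. Part of the excess may come from the shared controls, which are too few to be divided between the comparisons. Between different times, where the controls differ, r was 0.016 to 0.375. Shared calls exceeded those from list sizes in every such pair of times. GSK-J4 at 6 h and ZnSO4 at 3 h shared 340 rises and 261 falls (93.7 and 63.5 from list sizes, 121 opposite). GSK-J4 at 24 h and ZnSO4 at 6 h shared 245 and 398 (106 and 109, 149 opposite). Shared controls therefore do not account for the whole overlap, though their part at the same time stays open.

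**Figure D4:**
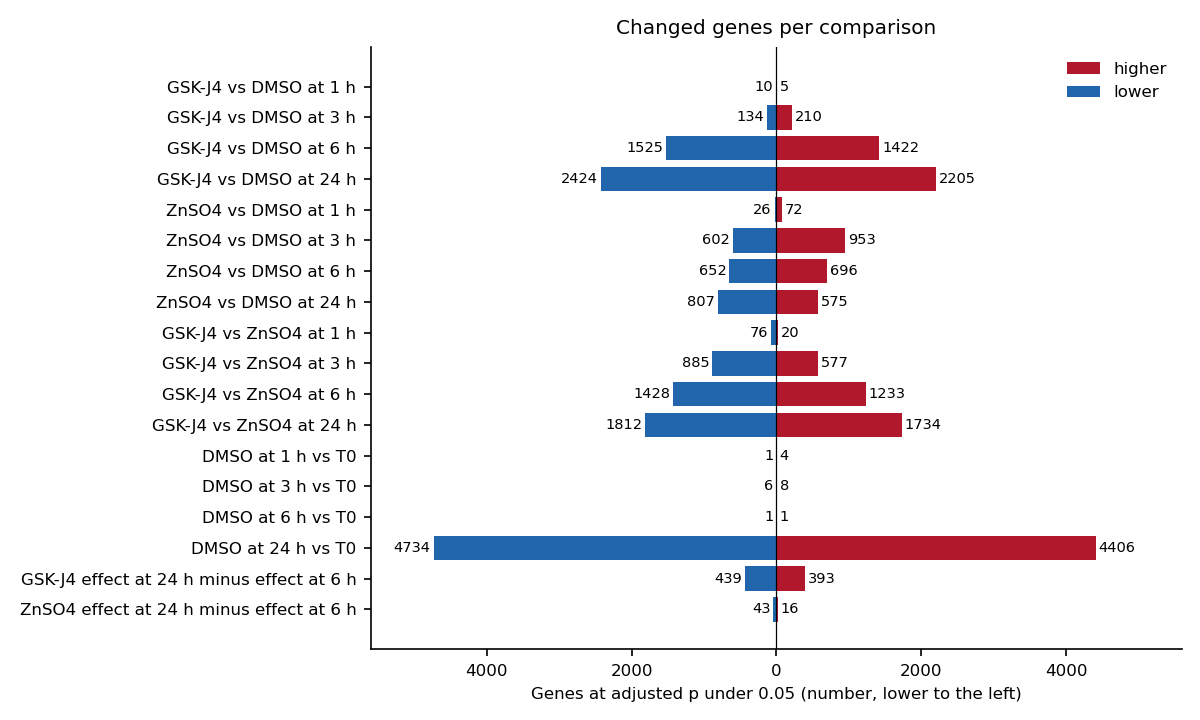
Number of genes (horizontal axis, lower to the left, higher to the right) at adjusted p under 0.05 in each of 18 comparisons (vertical axis). The bars grow with time for GSK-J4, up to 2205 higher and 2424 lower, and the longest belong to DMSO at 24 h against T0.

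Cells in DMSO differed little from T0 up to 6 h and widely at 24 h. No untreated cells of 24 h were sampled, so time, DMSO and handling are not separated. Against T0, the growth-response factor gene EGR1 (ENSG00000120738) rose at 24 h from 2.14 ± 0.740 to 191 ± 9.15 CPM (log2FC 6.52 ± 0.18, adjusted p = 3.8e-40). JUN (ENSG00000177606) rose from 36.2 ± 3.25 to 382 ± 18.5 CPM (log2FC 3.39 ± 0.07, adjusted p = 4e-45). MIR3142HG, the host gene of a microRNA, fell with log2FC −5.31 ± 0.20, STC2 with −2.69 ± 0.11 and HSPA8 with −2.33 ± 0.10 (adjusted p = 8.6e-33, 1e-31 and 9e-31). Immediate early genes rose in 18 of 19 (list adjusted p = 7.23e-25), hypoxia response genes in 12 with 1 falling (list adjusted p = 1.88e-09). The p53 targets rose in 11 of 17 with 3 falling (list adjusted p = 0.000264), and the BCL2 family in 7 of 14 with 2 falling (list adjusted p = 0.00154). All 13 mitochondrially encoded mRNAs rose (list adjusted p = 6.28e-08; adjusted p = 0.177 with an estimated correlation). Heat shock genes fell in 12 of 18 with 2 rising (list adjusted p = 4.7e-05; adjusted p = 0.339 with an estimated correlation). In numbers, 9140 genes changed at 24 h (4406 higher, 4734 lower; 1066 and 1868 at least 2-fold). With library totals as the scale 2769 were higher and 6519 lower, and the median log2FC of all genes moved to −0.239. At 1, 3 and 6 h only 5, 14 and 2 genes changed (1112, 1872 and 1778 at unadjusted p under 0.05), with counts of 13, 140 and 45 by DESeq2. SLC30A1 at 3 h was among them (log2FC 0.43 ± 0.09, adjusted p = 0.024) but not in every alternative, and the counts swing with the T0 libraries: without replicate 1 of T0, 703 genes were called at 3 h and 801 at 6 h.

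The effect of GSK-J4 differed between 6 and 24 h in 832 genes and that of ZnSO4 in 59. Taking each effect over DMSO of its own time, the log2FC of GSK-J4 was lower at 24 h for ATF3, a stress-induced transcription factor gene (difference in log2FC −2.47 ± 0.16, adjusted p = 2.3e-18), the amino acid transporter gene SLC38A2 (−1.72 ± 0.10, adjusted p = 1.1e-21) and MT1X (−1.93 ± 0.21, adjusted p = 7.2e-10). It was also lower for SESN2 (−1.39 ± 0.12, adjusted p = 1.3e-13), PMAIP1 (−1.36 ± 0.10, adjusted p = 9.2e-17) and SLC30A1 (−1.10 ± 0.11, adjusted p = 4.3e-12). For SLC30A1 the DMSO libraries rose from 53.2 to 72.95 CPM at 6 h to 109.9 to 116.6 CPM at 24 h. Those of GSK-J4 went from 228.4 to 239.6 CPM to 195.4 to 204.2 CPM. MT1X fell in the GSK-J4 libraries from 755.9 to 762.4 CPM to 471.7 to 552.1 CPM. In the DMSO libraries MT1X rose from 6.488 to 7.92 CPM to 16.57 to 19.72 CPM. PMAIP1 and ATF3, which rose at 6 h, were lower with GSK-J4 than in DMSO at 24 h (log2FC −0.28 ± 0.07 and −0.25 ± 0.08, adjusted p = 0.00061 and 0.02), but DMSO itself was higher there than T0 (1.54 ± 0.07 and 3.71 ± 0.12, adjusted p = 5.7e-28 and 2.2e-36). The call of ATF3 at 24 h was lost with library totals, without replicate 3 of DMSO and without replicate 1 of GSK-J4. The log2FC was higher at 24 h for BHLHA15, the secretory cell factor MIST1 (1.68 ± 0.26, adjusted p = 5.6e-06) and for KLF2 (1.17 ± 0.19, adjusted p = 1.3e-05). Of the 832 genes 393 were higher and 439 lower (550 and 292 by library totals). ATF4 targets were lower in 18 of 33 with 1 higher (list adjusted p = 2.56e-34; 19 lower and 2 higher when adjusted over the list alone). A lower effect need not be a lower level with GSK-J4, since members also moved in DMSO at 24 h against T0. There PPP1R15A and ATF4 were higher (log2FC 4.19 and 1.18) and STC2 was lower (−2.69). For ZnSO4 16 were higher and 43 lower (37 in all without replicate 2 of ZnSO4 at 24 h). HMOX1 (−1.55 ± 0.16, adjusted p = 9.9e-10), MT1X (−1.3 ± 0.22, adjusted p = 0.00015) and the collagen chaperone gene SERPINH1 (−1.05 ± 0.16, adjusted p = 3.8e-05) had a lower log2FC at 24 h, and MCL1, an anti-apoptotic gene, a higher one (0.61 ± 0.07, adjusted p = 4.2e-09). MT1X itself did not fall with ZnSO4 (1150 to 1419 CPM at 6 h, 1187 to 1513 CPM at 24 h). Its level in DMSO was higher at 24 h (16.57 to 19.72 CPM) than at 6 h (6.488 to 7.92 CPM). Hypoxia response genes were lower in 3 of 19 (list adjusted p = 5.08e-07).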

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

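Which patterns to weigh was chosen after seeing the results, as were the tests of another cell line, of separate handling, of metallothionein proportions and of their sum; the regroupings and the tests of GC content and length and of SLC30A1 in a single DMSO library had been set before. The results given first are differences between the 6 h and 24 h effects of a compound, found by a direct test of the difference. For GSK-J4 832 genes differed. The largest gains at 24 h were NAALAD2 (1.80), TEF (1.79), IQANK1 (1.75) and BHLHA15 (1.68), and the largest losses MT-TI (−2.55), ATF3 (−2.47), ISL2 (−2.42) and CRHR2 (−2.38). For ZnSO4 59 genes differed, with gains of HSPA8P1 (1.295), ZNF222 (1.16), HSPA8 (0.96) and SKI (0.81) and losses of HMOX1 (−1.55), MVP-DT (−1.40), MT1X (−1.3) and LDLRAD4 (−1.22). Gains and losses are of the effect over DMSO: the level of MT1X did not fall with ZnSO4 but was higher in DMSO at 24 h. HSPA8P1 may share reads with HSPA8, and MT-TI is a mitochondrial tRNA gene whose reads may overlap its neighbours, though neither was tested.

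Among 100 regroupings of the 12 libraries of each difference, 13 called at least as many genes as the actual grouping for GSK-J4 and 12 for ZnSO4, counting the actual one. The highest other counts, 5489 and 2584, came from the grouping that adds the effects of the compound at the 2 times in place of subtracting them. Of the 85 regroupings that mix treated and DMSO libraries at both times, none called as many, the highest being 1 for GSK-J4 and 3 for ZnSO4. The large counts thus come from the treatment effects that the unmixed regroupings keep, and the share of 100 is no measure of chance here. The 85 mixed regroupings are no such measure either, since mixing puts treatment effects into the spread within groups. Under the rule set beforehand, the shares of 13 and 12 of 100 left chance open for both differences.

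The 9 libraries of 24 h stand apart from the other 30. Another cell line at 24 h was ruled out: 0 genes were above 5 CPM in all libraries of one side and below 0.2 CPM in all of the other, and the immunoglobulin gene IGKV3-15 led the kappa variable counts in 39 of 39. Bias from GC content or transcript length was ruled out as the source, since 8982 genes were called in DMSO at 24 h against T0 after the trend was removed and 8944 before, over 14131 genes with a known value. Of these, 8466 were called both times in the same direction. For GSK-J4 against DMSO the correction kept 2573 of 2911 calls at 6 h and 3993 of 4558 at 24 h. It kept 2195 of 2637 for GSK-J4 against ZnSO4 at 6 h, and 1328 of 1370 for ZnSO4 against DMSO at 24 h. Separate handling of these libraries may contribute to the component with 54.44% of the variance, and 24 h of growth may as well; no labels tell them apart. Comparisons within 24 h do not cross this division.

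Metallothioneins were higher with GSK-J4, which is not a metal salt. Carry-over of reads from ZnSO4 libraries does not account for it at 3, 6 and 24 h, since MT1E per MT1G read in GSK-J4 was at most 0.473 of that in ZnSO4, without overlap of libraries. At 1 h it is not the whole cause: excess MT1X per excess MT1G was at least 1.57 in GSK-J4 and at most 1.28 in any ZnSO4 library (group value 1.72 over replicates 2 and 3 of DMSO, 95% counting interval 1.53 to 1.96), though a part from carry-over stays open. Reads moved between copies do not account for a rise of the family, because the summed CPM of 20 copies and pseudogenes was 165 times that in DMSO at 3 h; how reads divide between single copies stays open. An activation of the metal-responsive factor MTF1 by GSK-J4 is a hypothesis only, since no free zinc was measured and no cells without MTF1 were sampled.

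Replicate 1 of DMSO at 1 h held 168 MT1G and 122 MT1X counts, above the other libraries of its group. Its excess of MT1X over MT1G reads was in the ratio 0.356 (95% interval 0.26 to 0.488, for counting error only). This lies within the 0.239 to 0.699 of treated libraries of 3 to 24 h and outside the 1.14 to 2.14 of treated libraries of 1 h. The pattern is consistent with carry-over of reads from a library rich in metallothioneins, the excess of MT1G being 1.11% of the mean MT1G of those libraries. A metal response of that culture is unlikely, because SLC30A1 was at 0.839 of the other 1 h DMSO libraries.

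For the comparisons of 3 libraries with 3, only 10 splits exist, too few for a share under 0.05. Every other split also mixes libraries of the compared groups, so a real difference enters the spread within groups and few genes can be called. Low counts in the other splits therefore do not measure noise between replicates. The actual grouping of GSK-J4 and DMSO was the only one of 10 to reach its count at 1, 3, 6 and 24 h (15, 344, 2947 and 4629 genes; highest other 0, 0, 1 and 2). That also held for ZnSO4 and DMSO (98, 1555, 1348 and 1382; highest other 2, 0, 3 and 1), for GSK-J4 and ZnSO4 (96, 1462, 2661 and 3546; highest other 1, 0, 0 and 0), and for DMSO at 24 h and T0 (9140; highest other 2). For DMSO at 1, 3 and 6 h against T0, 3, 2 and 3 of 10 splits called as many as the actual 5, 14 and 2 genes, with 14, 97 and 1246 in the highest other. Counts several times the actual one point to structure among those libraries. The T0 libraries differed from each other (chi-squared per gene 3.149 to 7.323). Replicate 3 of DMSO at 6 h also differed from its group (3.049 and 3.051, against 1.457 between replicates 1 and 2).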

How the results depend on the processing

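All choices in this part were made before the data were examined, except the fits without the 24 h libraries, with only these, or with a replicate block, chosen after seeing the data. The columns carry running sample numbers and a number after an S, and neither names a replicate. The replicate block therefore used the order within each group. Over all genes, deviations from the group means did not pair the libraries throughout: in 0 of 16 comparisons were all 3 correlations at the same position over 0.1 (mean 0.0122, against −0.00609 at different positions). Only DMSO at 6 h against T0 had values over 0.1, with 0.119 at position 1 and 0.254 at position 3, beside 0.0116 at position 2. As a hint from the data, every library correlated best with its own position in 3 of 16. Replicate 1 also had the lowest HMOX1 in 8 of 8 treated groups and the lowest MT1X in all 4 ZnSO4 groups. A pairing for single genes is therefore not excluded. The replicate block gave 362 genes for GSK-J4 at 3 h and 1571 for ZnSO4 at 3 h, and 33 for DMSO at 3 h against T0. All other counts stayed within 1.5 times, and 13 calls of named genes were gained and none lost; lists were not refitted with the block. All comparisons of GSK-J4 and ZnSO4 with DMSO and with each other kept counts within 1.5 times the main one in every alternative that kept all their libraries, except GSK-J4 at 3 h fitted on its own groups (1072 in place of 344); the cause was not tested. DMSO at 1 h against T0 gave 0 genes with RLE factors, 0 with library totals, 31 without the filter, 13 with DESeq2, 0 on its own groups and 0 without the 24 h libraries. DMSO at 3 h against T0 gave 78 without the filter, 140 with DESeq2 and 0 on its own groups. DMSO at 6 h against T0 gave 0 with library totals, 60 without the filter, 45 with DESeq2, 0 on its own groups and 0 without the 24 h libraries; the cause was not tested. The edgeR counts at unadjusted p under 0.05 were 1112, 1872 and 1778 for these times. Scaling by library totals also moved the median log2FC of all genes at 24 h of GSK-J4 to 0.114 from 0.022, and at 24 h of DMSO against T0 to −0.239 from −0.0174.

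Leaving out 1 library at a time, counts ranged for GSK-J4 against DMSO from 10 to 16, 246 to 268, 2262 to 2549 and 3786 to 4165 at 1, 3, 6 and 24 h. They ranged for ZnSO4 from 66 to 94, 1131 to 1406, 876 to 1162 and 809 to 1141, and for GSK-J4 against ZnSO4 from 71 to 103, 979 to 1331, 2044 to 2312 and 2895 to 3157. For DMSO against T0 they ranged from 1 to 58, 1 to 703, 0 to 801 and 8571 to 8952, and for the differences between times from 635 to 748 (GSK-J4) and 37 to 61 (ZnSO4). The counts of 876 at 6 h and 809 at 24 h of ZnSO4 came without replicates 3 and 2 of ZnSO4.

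Of 396 list tests 170 were called, 170 with RLE factors, 189 without the filter and 99 with an estimated correlation, which assumes less about how genes of a list move together. The shared response at 1, 3, 6 and 24 h held 4, 22, 29 and 31 genes when at least a 2-fold change was asked of both compounds, in place of 7, 189, 559 and 774, and 5, 190, 570 and 715 with DESeq2. Among named genes, direction turned for MT1G in DMSO at 1 h against T0 without replicate 1 of DMSO (−0.0792, against 4.66 without replicate 1 of T0) and for SLC39A6 in DMSO at 24 h against T0 with library totals (−0.0041). Calls of named genes lost and gained were 75 and 53 without the filter, 44 and 26 with library totals, 35 and 20 with DESeq2, 24 and 64 on own groups, 11 and 1 with RLE factors, 20 and 1 without the 24 h libraries, and 0 and 13 with only these. Leaving out single libraries lost 640 over all repeats, gained 154 and left 11175 the same. At 4347745 to 10695671 counts per library, 3 counts equal 0.2805 to 0.69 CPM. Changes of 1.5-fold were found for 62.5% of simulated genes, all drawn above 2 CPM, so the rate for lower genes was not tested.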

Other observations

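The comparisons of response sizes here were chosen after seeing the results. The difference in CPM between GSK-J4 and DMSO, as a share of that between ZnSO4 and DMSO, was 11.9, 41.9, 55.1 and 40% for the metallothioneins at 1, 3, 6 and 24 h. For HMOX1 it was 8.39, 2.98, 5.36 and 26.2%, although HMOX1 was not called with GSK-J4 at 1 h (log2FC 0.19 ± 0.13, adjusted p = 1). For HSPA6 it was −3.72, 0.657, 6.96 and 98.9%. The share at 24 h is imprecise, since the rise of HSPA6 with ZnSO4 was smaller there (log2FC 2.07 ± 0.47) than at 3 h (5.39 ± 0.25). Other genes raised at least 2-fold by ZnSO4 had a median share of 5.83, 18.8, 30.1 and 40.5%. Their quartiles were −2.04 to 14.1, 5.16 to 44.1, 10.5 to 48.9 and 16.1 to 57.6%. The metallothionein share lay within these at 1, 3 and 24 h and above them at 6 h.

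SLC7A11, the cystine transporter gene among the ATF4 targets, stood at 89.9 ± 4.02 CPM at 6 h of GSK-J4, 19.2 ± 0.834 CPM with ZnSO4 and 19.1 ± 1.80 CPM in DMSO (SD, n = 3). BHLHA15 was at 13.4 ± 0.848 CPM at 24 h of GSK-J4, 3.09 ± 0.417 CPM with ZnSO4 and 5.52 ± 0.767 CPM in DMSO.

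The share of mitochondrially encoded reads was 4.606 ± 0.217% with GSK-J4, 5.344 ± 0.175% with ZnSO4 and 5.007 ± 0.228% in DMSO at 24 h. At 6 h it was 3.077 ± 0.071%, 3.791 ± 0.076% and 3.518 ± 0.041%. With ZnSO4 at 6 h 11 of 13 pseudogenes of FTH1 were also higher, with a median log2FC of 1.68 beside 1.73 for FTH1 itself, so that reads of 1 source cannot be told from the others.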
